A study of Mus musculus with 6 samples.

How the data were processed

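The series holds ChIP-seq of mouse cells differentiated from embryonic stem cells, and the whole-cell extract is the control. Per the labels, 5 samples are immunoprecipitates of V5-tagged Cdx2 or H3K27me3 and 1 is the whole-cell extract of day 5 motor neurons. Each group has 1 sample, so there is no replicate. Chromatin was sheared to about 500 bp per the labels. Per the submitters' processing notes, the whole-cell extract was aligned to the mm8 build with Bowtie 0.9.9.2, whereas the notes of the immunoprecipitates name CASAVA 1.7 and mm9. The deposited values are in a unit other than counts: each line is 1 alignment of 1 read, with its position counted from 0, its bases and qualities, the number of other placements and the mismatches. The options of the aligner were not stated. Every read had at most 2 lines and a length of 36 bases. A read with 2 lines may have further placements that are not listed, so counts with both placements need not be complete.

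Counts were made from the alignments. A read with 1 line was taken as placed once, and 1 read per 5′ end and strand was kept unless stated. Positions are printed counting from 1 on mm8. Bins of 100 kb served for dosage, and bootstrap intervals came from 2000 draws of blocks of 1 Mb. The CpG ratios matched on the GC content of the surroundings had 200 draws. The interval of the mitochondrial ratio is an exact Poisson interval. Shares have exact Clopper-Pearson intervals. The 9750389 reads placed once give a median of 345 distinct ends per autosomal bin of 100 kb, and 4 per occupied bin of 1 kb, which is too shallow for single promoters. Extreme bins are bins of 1 kb with more than 10 times that median, leaving out the mitochondrial genome.

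GC content was taken from the reads in a bin, since a genome of this build was not used here. For matching, bins were divided by the median of autosomal bins in the same of 10 groups of GC content, or in the same of these and of 5 groups by the number of doubly placed alignments. The latter number follows in part the copy number that it is used to correct. Mismatches were counted at bases 6 to 25 of a read with a base quality of at least 25, in windows of 1 Mb with at least 20 kb of such bases. Agreement between reads compared up to 3 reads over a position in file order. Repeat families were counted by exact match of short sequences of 18S, 28S and 5S ribosomal RNA, major satellite, minor satellite and telomere repeat, written from general knowledge after the highest bins had been seen.

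The depth, dosage and extreme-bin values were defined before the data were examined, with the alternatives for duplicates, bin width, mismatches and threshold. A comparison of density by GC content had been planned on a reference genome, with and without duplicates; taking GC content from the reads was chosen after seeing the data. So were the matching, the mitochondrial ratio, the neighbours of CpG-rich reads, the mismatch windows, the runs, the repeat sequences and their limits. The 5 highest bins of 1 kb are named by a rule fixed beforehand; other regions are named because their values stood out. Gene lists for Hox clusters, Cdx genes, motor neuron, pluripotency and other genes had also been fixed. They were not analysed here, because the gene coordinates at hand belong to another build than mm8 and positions were not converted.

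The procedures were tested on simulated data. With the real relation of count to GC content, chromosome 11 simulated at 1.5 was recovered at 1.46 after matching. In the same simulation chromosome 8 at 1.25 was recovered at 1.21 and chromosome X at 0.5 was recovered at 0.491. The matching on doubly placed alignments was not tested in this way. Simulated variants on both copies with errors gave an agreement of 70.6% for the second read, where 71.4% was calculated. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.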

Results

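The study profiled the transcription factor Cdx2 and the Polycomb mark H3K27me3 in mouse cells differentiated from embryonic stem cells. It comprises 6 samples: 2 chromatin immunoprecipitations of V5-tagged Cdx2 at day 4, 3 of H3K27me3 at day 5, and 1 whole-cell extract of day 5 motor neurons. All had received retinoic acid and a hedgehog agonist except the H3K27me3 sample given only doxycycline and bFGF. A whole-cell extract is sheared, crosslinked chromatin sequenced without an antibody, and it shows the background against which binding sites are called. Its cells had received 1 µM retinoic acid and 0.5 µM of a hedgehog agonist, and their label names the Ainv15 stem cell line. The whole-cell extract was the 1 library whose alignments were used; the 5 immunoprecipitated libraries were not analysed here. No comparison between groups was therefore made, and the values describe the genome and the background of 1 library without replicate. Intervals are 95% intervals and cover counting error or the spread along the genome, not variation between cultures.

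Most reads placed once came from distinct fragment ends, and few were duplicates. It held 13409439 aligned reads of 36 bases, of which 9750389 (72.7%) had 1 placement and 3659050 (27.3%) had 2 placements listed. Reads with 1 placement fell on 9570301 distinct 5′ ends, 98.2% of their number. A further 180088 reads (1.85%) lay at an end that was already occupied, where an even spread within bins of 100 kb would give 13299 (0.136%). The minus strand took 50.0% of the reads placed once. It took 29.4% of the alignments of doubly placed reads, so the listed placements of these reads were not balanced between strands.

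Read density over the autosomes rose steeply with GC content. Among 23844 autosomal bins of 100 kb, sorted into 10 groups of equal size by the GC content of their reads, the median count rose in every step. It was 208 distinct ends in the group with a median GC of 37.3% and 817 in the group with a median of 55.5%. The highest group thus had 3.93 times the density of the lowest (95% interval 3.85 to 4.00). The size of this ratio depends on placement, as the median bin held 216 doubly placed alignments in the lowest group and 139 in the highest. It was 3.62 in bins with few doubly placed alignments and 2.62 with both placements of every read. The middle 50% of bins spanned 183 to 231 ends in the lowest group and 729 to 938 in the highest, so the groups at the extremes did not overlap there.

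**Figure D1:**
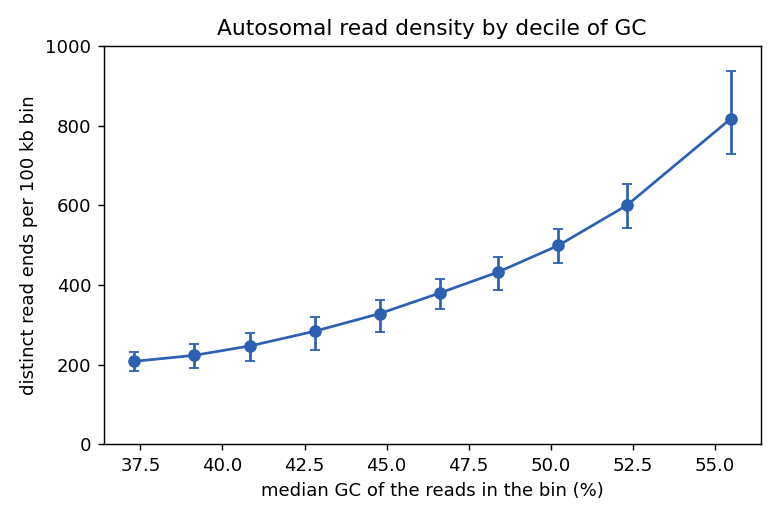
Distinct read ends per 100 kb bin (vertical axis) against the median GC content of the reads in the bin in percent (horizontal axis), for 10 groups of autosomal bins; points are medians and bars span the quartiles. The medians rise from 208 to 817.

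Chromosomes differed in read density, and among the autosomes this difference followed their base composition. Dosage is the median count per 100 kb bin of a chromosome over the median of 345 for all autosomal bins. Without correction chromosome 11, whose bins had a median GC of 48.9%, was highest of the 19 autosomes at 1.301 (1.18 to 1.44). Chromosome 3, at 43.3% GC, was lowest at 0.867 (0.812 to 0.933). In all, 6 autosomes lay more than 10% from the autosomal median, and the SD over autosomes was 0.111. When each bin was set against autosomal bins of like GC content, chromosome 11 came to 1.01 (0.998 to 1.03) and chromosome 3 to 1.00 (0.981 to 1.02). The autosomes then ranged from 0.951 on chromosome 7 to 1.02 on chromosome 16, with an SD of 0.0186, and 0 of them lay more than 5% away. The intervals of chromosome 7, 0.923 to 0.976, and chromosome 17, 0.938 to 0.995, lay below 1, and that of chromosome 2, 1.01 to 1.04, lay above it. With bins matched also on the number of doubly placed alignments, chromosome 7 still lay below 1 (0.938 to 0.978). The intervals of chromosomes 17 and 2 then reached 1, while those of others, such as 14 (0.963 to 0.990) and 11 (1.010 to 1.028), did not. In simulated data matched on GC content, autosomes left at 1 came out up to 0.045 away from it. Other autosomes, chromosome 11 among them, were simulated with gains there, and their bins were part of the medians used for matching. That value therefore cannot give the error of data without such gains, and the shifts of chromosomes 7, 17 and 2 cannot be judged by it. None of these shifts was tested as a change of copy number. After matching, no autosome had the dosage of 1.5 that an added copy in every cell would give.

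In reads placed once, the X and Y chromosomes had less than the autosomal density. Chromosome X had an uncorrected dosage of 0.314 (0.296 to 0.331), and its bins had a median GC of 40.7%. Set against autosomal bins of like GC content it came to 0.438 (0.426 to 0.452), and with bins matched also on the number of doubly placed alignments it came to 0.468 (0.459 to 0.474). Chromosome Y, which had 26 bins with reads placed once, gave 0.312 (0.114 to 0.503) without correction. It gave 0.469 (0.128 to 0.697) after matching on GC content. These bins held 2834 distinct ends, and the unplaced part of Y held 4972 more, so DNA of a Y chromosome was present. The interval for Y is too wide to set its dosage against that of X. Counting both placements of every read gave 0.613 for X and 1.13 for Y, so the low value of Y holds for reads placed once alone.

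**Figure D2:**
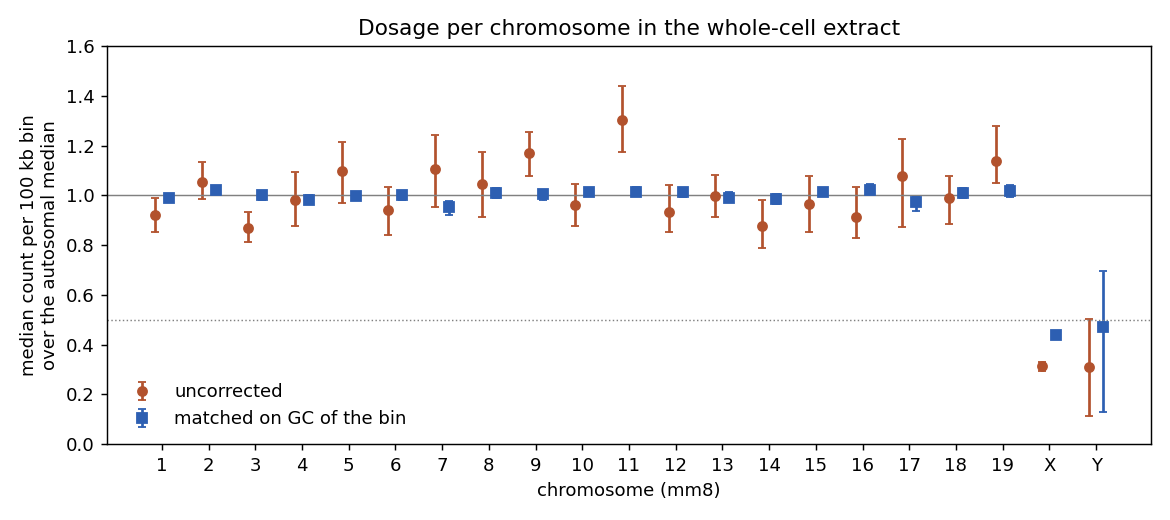
Dosage of each chromosome, as the median count per 100 kb bin over the autosomal median (vertical axis), before correction (circles) and with bins matched on GC content (squares); bars are 95% bootstrap intervals over blocks of 1 Mb. Chromosome 11 moves from 1.301 to 1.01 and chromosome X from 0.314 to 0.438, with dotted and solid lines at 0.5 and 1.

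The mitochondrial genome was covered more densely than the nuclear genome. It held 1599 distinct ends over 16297 bases, or 98.1 per kb, against an autosomal median of 3.45 per kb. The ratio was 28.4 (27.1 to 29.9), without matching on GC content, with which autosomal density rose steeply. The ratio depends on which reads are counted, in the mitochondrial and nuclear genomes alike. It was 40.8 with duplicates kept, from 2331 reads placed once, and 43.9 for distinct ends with both placements of every read. With both placements and duplicates kept it was 59.7, from 5357 reads.

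At a finer scale most of the autosomal genome was even. Of 2331 autosomal windows of 1 Mb, 2225 (95.5%) had a median dosage between 0.8 and 1.2 after matching on GC content and doubly placed alignments. There were 77 windows below and 29 above that range. Runs of 3 or more neighbouring windows below 0.75 occurred in 3 places of the mm8 build. The deepest lay on chromosome 14 from 41000001 to 44000000, with windows at 0.00607 to 0.156. The others lay on chromosome 7 from 12000001 to 15000000 (0.0271 to 0.497) and on chromosome 4 from 111000001 to 114000000 (0.137 to 0.628). All 3 were rich in doubly placed alignments: their median bins held 904, 566.5 and 307.5, where the median bins of chromosomes 14, 7 and 4 held 167, 177 and 176. The low counts of reads placed once there cannot be read as a loss of DNA. No run of 3 or more windows more than 25% above the autosomal median was found.

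A small set of sites drew far more reads than the rest. Whether they also give peaks in the immunoprecipitates was not examined. Of 2126018 bins of 1 kb with at least 1 end, 591 held more than 10 times the autosomal median of 4 distinct ends. The count depends on the reads used: it was 3303 with both placements of every read, and 276 at the same limit for reads whose name ends in 1. Together they held 41940 ends, or 0.438% of all. Chromosome 11 had 110 of these bins, of which 67 lay between 3004001 and 3100000, at the start of its assembled sequence. Chromosome X had 22, of which 21 lay between 165321001 and 165344000, towards the end of the chromosome. Chromosome 17 had 54.

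By distinct ends, the 5 highest bins all lay on chromosome 17 between 39451001 and 39457000, with GC contents of 63.4% to 71.4%. The highest, 39452001 to 39453000, held 1529 distinct ends, or 382 times the median. The next, 39453001 to 39454000, held 1348. The bins starting at 39451001, 39456001 and 39454001 held 921, 915 and 750. These counts are limited by the number of positions: the highest bin had ends at 76.5% of all positions on both strands. With duplicates counted it held 4083 reads, or 1021 times the median. By reads in place of distinct ends, the chromosome 2 bin at 98467001 to 98468000 ranked after the first 2 of these bins and above the other 3, with 2426 reads. The whole stretch took 13526 reads, which is 0.139% of the reads placed once. Short sequences of the 18S ribosomal RNA were found in this stretch. The first of 3 such sequences had 42 alignments in the bin that starts at 39456001. The others had 10 and 41 in the neighbouring bin at 39455001, which is not among the 5 highest. The bins starting at 39451001, 39452001, 39453001 and 39454001, with the 2 highest among them, held 0 alignments of the 18S sequences. Most reads with these sequences also had a placement on another chromosome, such as 22 alignments of the first sequence on chromosome 4 at 78245001. By distinct ends the next sites in rank were the chromosome 11 bin at 3093001 to 3094000, with 521 distinct ends, and the chromosome 2 bin at 98467001 to 98468000, with 444. Satellite sequences were found in this chromosome 2 bin. The 2 major satellite sequences had 5349 and 5007 alignments there, and the minor satellite sequence had 9697, nearly all of doubly placed reads.

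Reads that contained CpG dinucleotides lay in denser surroundings than reads of like GC content without them. CpG dinucleotides are rare in the mouse genome outside CpG islands, which mark many promoters. Density was measured as the number of other distinct ends per kb at 100 to 500 bp on either side of a read, on autosomes outside the extreme bins. Among reads of 52.8% to 61.1% GC, those with 3 or more CpG had 12.1 neighbours per kb (11.9 to 12.3) and those with none had 7.21 (7.06 to 7.35). The ratio was 1.67 (1.65 to 1.70). It fell to 1.33 at 500 to 1000 bp, 1.14 at 1000 to 2000 bp and 1.06 at 5000 to 10000 bp. In reads of 41.7% to 50% GC it fell less far, from 1.69 to 1.22 (1.21 to 1.24) at 5000 to 10000 bp. In reads of 63.9% to 72.2% GC the ratio began at 1.78 and crossed below 1 beyond 2000 bp, to 0.926 (0.916 to 0.937). This matching is on the GC content of the read and not on that of its surroundings.

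**Figure D3:**
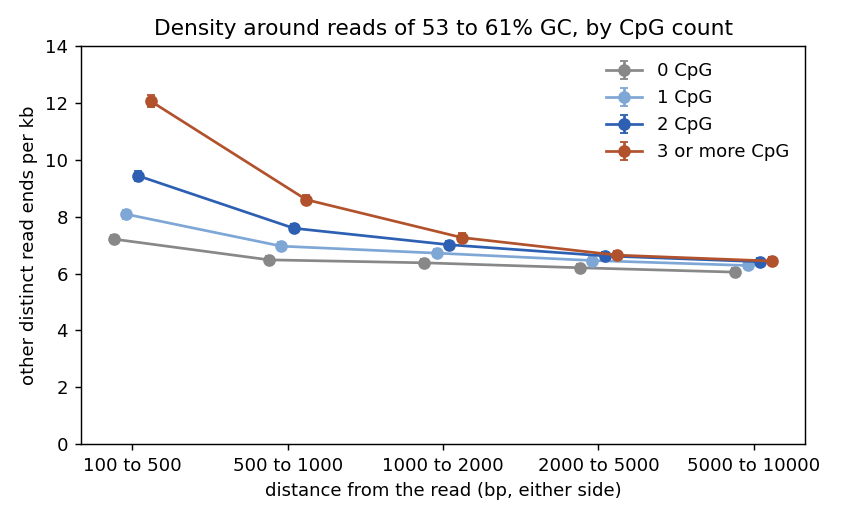
Other distinct read ends per kb (vertical axis) by distance from a read in bp (horizontal axis), for reads of 52.8% to 61.1% GC with 0, 1, 2 or at least 3 CpG; bars are 95% bootstrap intervals. Reads with at least 3 CpG start at 12.1 per kb and reads with 0 at 7.21, and the lines approach each other with distance.

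Differences from the mm8 reference were unevenly spread along the chromosomes. Counting bases 6 to 25 of distinct reads placed once, at a base quality of at least 25, there were 405065 mismatches, or 2.65 per kb. The median over 2338 autosomal windows of 1 Mb was 2.15 per kb. The lowest 5% of windows lay under 0.632 per kb and the highest 5% above 8.59, a ratio of 13.6 (12.80 to 14.02). The SD between windows was 2.37 per kb, where counting error alone would give 0.224. Chromosome X was low, with a median of 0.969 per kb over the 52 windows that had at least 20 kb of counted bases. Chromosome 10 was nearly as low, with a median of 1.01 per kb over 127 windows. The highest window of X, from 165000001 to 166000000, holds 21 of its extreme bins and stood at 9.03 per kb. That window was rich in doubly placed alignments, at 2381, where the median bin of X held 240. The next highest window of X, from 148000001, stood at 2.28.

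Windows with high rates lay next to each other more often than in shuffled windows. Of 2390 windows, 361 had more than 2 times the autosomal median, and 131 of these lay in 18 unbroken blocks of 5 or more windows. The others lay in shorter runs or alone. In 1000 shuffles of the same windows there were at most 2 such blocks, and the longest run was 8 windows. The longest block ran over 14 windows on chromosome 15 from 30000001 to 44000000, at 8.18 mismatches per kb. Chromosome 14 had a block from 6000001 to 19000000 at 8.56 per kb. Chromosome 7 had one from 48000001 to 59000000 at 9.93, and chromosome 8 had one from 34000001 to 45000000 at 9.36. On chromosome 1 the longest block ran from 170000001 to 178000000 at 8.49 per kb.

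Overlapping reads gave the same mismatched base far more often in these windows than in windows with low rates. Where the first read over a position differed from the reference and a second read covered it, the second had the same base at 84.8% of 10262 positions (exact 95% interval 84.1 to 85.5) in the 361 windows with high rates. In the 829 windows whose rate was below the autosomal median divided by 1.5, it did so at 22.5% of 2690 positions (20.9 to 24.1). In the 1200 windows with rates between these it did so at 73.2% of 12978 positions (72.5 to 74.0). Agreement was thus not confined to windows with high rates. Transitions made up 67.6% of the mismatches in the windows with high rates and 62.9% in those with low rates.

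**Figure D4:**
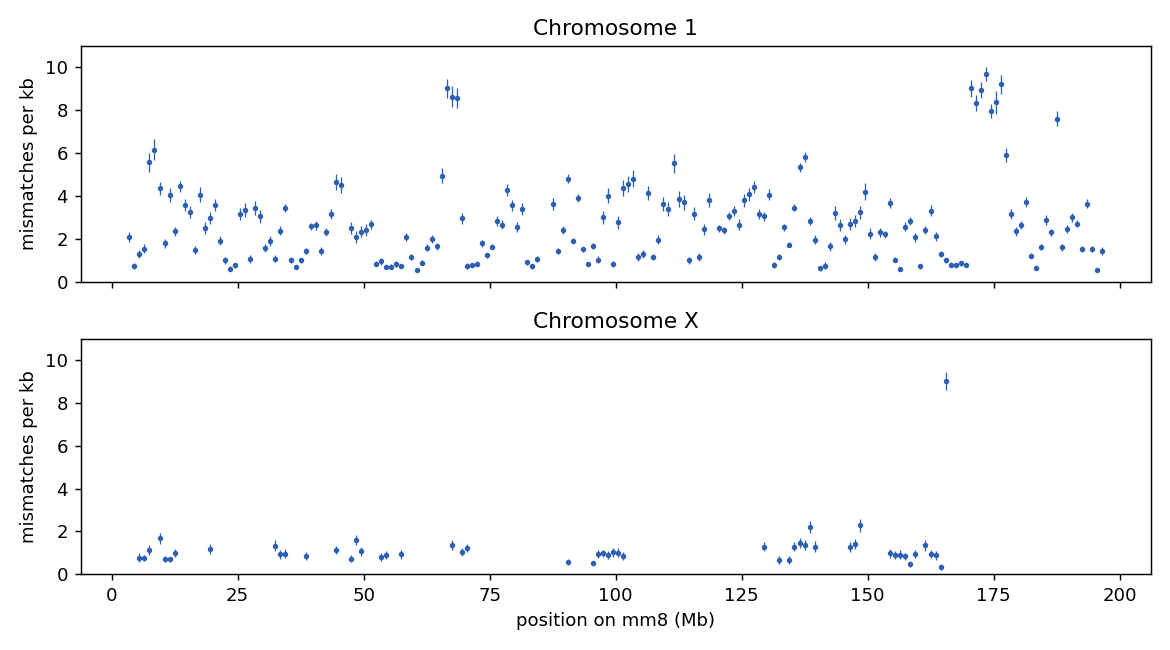
Mismatches per kb of counted bases (vertical axis) in windows of 1 Mb along chromosomes 1 and X, by position on mm8 in Mb (horizontal axis); bars are the counting error (1 SE). On chromosome 1 the block from 170000001 to 178000000 stands at 8.49 per kb, and the windows of X have a median of 0.969, with 1 window at 9.03.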

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

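Reads with 2 placements take no part in most of the values above, and they held sequences of several repeat families far above the 3 reads that a count of 0 allows. These counts were chosen after seeing the data. The first of 2 major satellite sequences, the repeat beside mouse centromeres, was found in 34902 doubly placed reads, and the second in 11717. With reads placed once included, the first sequence was in 35022 reads, or 0.261% of all (exact 95% interval 0.258 to 0.264). The minor satellite sequence, at the centromere, was in 15452 doubly placed reads. The telomere repeat was in 7766. The counts of the 2 major satellite sequences differ from each other, so they do not give the size of the family. The ribosomal sequences were rarer: 42, 10 and 41 reads held the 3 sequences of 18S, and 38 reads held that of 5S. The 28S sequence was in 0 reads, from which nothing follows, as only aligned reads are listed and the sequence was written from memory. No biological explanation was tested for these counts.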

How the results depend on the processing

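Fixed before the data were examined were keeping duplicates (dosage, extreme bins, and GC groups, then planned on a reference genome), bins of 1 Mb (dosage), reads without a mismatch (depth, dosage) and thresholds of 5 and 20 times the median (extreme bins). All other alternatives, with all those of the CpG, mismatch and mitochondrial ratios, were chosen after seeing the data. With duplicates kept, bins of 1 Mb or reads without a mismatch, all 21 chromosome dosages stayed inside their intervals, as they did for both parts of the lane and for reads whose name ends in 1. Matching on GC content moved 8 of them: among them chromosome 3 to 1.00, 7 to 0.951, 11 to 1.01 and X to 0.438. Matching also on the number of doubly placed alignments gave 1.005 for chromosome 3, 1.02 for 11, 0.468 for X and 0.594 for Y. Matching on their share instead gave 1.004, 1.01, 0.525 and 0.575; it was run first and set aside once its values were seen, because the share rises by construction where the count being corrected is low. Whether X lies under or over 0.5 thus depends on this choice. Counting both placements of every read gave 0.613 for X and 1.13 for Y, which turns the direction for Y. The mitochondrial ratio was 40.8 with duplicates kept, 43.9 with both placements and 59.7 with both placements and duplicates kept. The number of extreme bins was 741 with duplicates kept, 17616 at 5 times the median, 89 at 20 times, 3303 with both placements and 1442 for reads whose name ends in 1. In the last case the median fell from 4 to 3, which lowers the limit; with the limit of all reads it was 276. The share of distinct ends was 98.6% without mismatches and 98.4% for reads whose name ends in 1. The ratio between the highest and the lowest GC group was 4.04 for those reads, 3.62 in bins with few doubly placed alignments and 2.62 with both placements. The CpG ratio was 1.78 in reads of 63.9% to 72.2% GC and stayed in its interval in the other 4 settings. The mismatch ratio was 10.9 at a quality of at least 20 and 15.9 at 30. Where values moved and no reason is given, the cause was not tested. Not run were GC deciles on the reference genome and all alternatives for promoters, Hox clusters and Cdx2 exons. No paired analysis was possible because 1 library was used.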

Other observations

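The tests of chromosome dosage and of mismatch windows were chosen after the results they concern had been seen. The tests of the surroundings of CpG-rich reads were written down before their results, though after the pattern had been seen; the check with more reads per neighbourhood was added after it.

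The density of chromosome 11 may follow from its base composition. Its dosage of 1.301 came to 1.01 when bins were matched on GC content. A gain of this chromosome in all cells is argued against by the upper end of that interval, 1.03, since a simulated dosage of 1.5 was recovered at 1.46. A gain in a small share of cells stays open. For chromosome X, in the 442 bins under the autosomal median number of doubly placed alignments, the GC-matched dosage was 0.504 (0.492 to 0.514), so base composition and repeats may account for values below 0.5 elsewhere. With a limit of 0.5 times that number for X, 108 bins gave 0.524 (0.508 to 0.544), which lies above 0.5, so the value moves with the limit. The upper end of the first of these, 0.514, argues against 2 X chromosomes in all cells, and reads on Y are in line with 1 X and 1 Y chromosome.

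The windows with high mismatch rates may lie where the genome of the line differs from the reference strain on both copies. Agreement was calculated for these 361 windows, of which 131 lay in blocks of 5 or more, and not for the blocks alone. Sequencing error is argued against by the second read, which had the same base at 84.8% of positions in windows with high rates. Reads misplaced from a mixture of repeat copies are argued against as the whole cause. In the 172 such windows with few doubly placed alignments the second read had the same base at 90.8% of 5223 positions (exact 95% interval 89.97 to 91.56). Misplaced reads that all came from 1 differing copy would also have the same base, so agreement cannot speak against them. In the same 172 windows, where the first 2 reads had the same base, the third had it too at 99.3% of 431 positions (97.98 to 99.86). A difference on 1 of 2 copies would give a share nearer 50%. In all windows with high rates this share was 93.3% of 1112 positions, so repeats may add to part of them. In the 1200 windows with rates between the high and the low ones it was 97.3% of 818 positions. Such differences are therefore not confined to windows with high rates. The share was lower in the 829 windows with low rates, at 88.5% of 78 positions (79.2 to 94.6). In the 52 windows of X, whatever their rate, it was 76.9% of 39 positions (60.7 to 88.9). If the cells hold 1 X chromosome, a difference on 1 of 2 copies cannot lower the share there, so it can drop for other reasons. The strain of the line is not stated in the labels, and no sequence of another strain was compared.

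For the density around CpG-rich reads, copies of 1 fragment read from both of its ends would lie on opposite strands. They are argued against as the whole cause by neighbours on the same strand, among which the ratio was 1.66 (1.64 to 1.69). The GC content of the surroundings cannot be told apart from another cause. With this GC content taken from reads of odd tiles and the density from even tiles, the ratio was 1.64 before matching and 1.34 (1.33 to 1.36) after, which is above the limit of 1.3 set beforehand. By that limit the result counted against the GC content of the surroundings as the cause. The limit made no allowance for noise, and a neighbourhood with 1 read gives a noisy GC content. The result was therefore changed to undecided after a check with more reads, which was added once it had been seen. Where at least 5 reads gave the GC content, the ratio went from 1.44 to 1.19 (1.177 to 1.201), and with at least 8 it went from 1.31 to 1.14 (1.128 to 1.152). Asking for more reads also selects dense neighbourhoods, which narrows the ratio by itself. Open chromatin that shears more readily stays a candidate explanation, untested.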
